A study of Homo sapiens with 8 samples.

How the data were processed

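The series holds 8 one-colour (Cy3) Agilent arrays of total RNA from EndoC-βH2, an established human pancreatic beta cell line. Per the labels' protocols, cells grown in 5.6 mM glucose were transfected with an siRNA pool against RFX6 (about 30 nM) or a non-targeting pool (siNT) and harvested 72 h later. Each group has 4 arrays. The labels do not say whether the replicates were separate cultures, so p-values measure the spread between these samples, which may be partly technical.

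The intensity values of each array were made with Agilent Feature Extraction 10.10.1.1, per the file headers, which also record 1 slide, 1 scan time, and spatial and multiplicative detrending for the processed signal. Each array holds 58717 spots outside the controls, which make up 42405 probes. No spot outside the controls was saturated. Spots with an outlier mark (270 to 512 per array) were left out of the probe averages, unless all spots of a probe on that array were marked. The deposited series table holds log2 values, and no label states how they were made. In sorted order they equal quantile-normalized log2 median signals of the same 8 arrays, and all 8 columns followed their own array best. Each column has a median of 7.71, and genes were not centred.

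The rows of the deposited series table were then set against the scanner values one by one. Of its rows, 203 did not hold the values of their own spot within a tolerance of 0.05 on the log2 scale, and the RFX6 row was among them. Each of the 203 rows held the values of another of these rows, to within 0.013. Down the table, the siRFX6 minus siNT difference that these rows held followed the row number (Spearman's rho 0.991 across rows, which are not independent replicates), while the difference measured at their own spots did not (rho -0.146). For the 61 affected probes with repeat spots, the median range between repeat spots was 1.91 in the table and 0.15 in the scanner values. All results therefore come from the scanner files. The series table serves only as an alternative, as given and, chosen after seeing the data, without the genes of the displaced rows. Whether the displacement is in the deposited record or arose when the copy used here was prepared is not known.

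Signals were taken as log2 of the processed signal minus the 75th percentile of each array's spots, controls left out, and spots of a probe were averaged. Probes well above background on at least 4 of 8 arrays, whichever their group, entered the test, and the probe with the highest mean signal stood for a gene, which left 24427 genes. Names came from the files and were updated through a RefSeq gene table (GRCh38.p14, used for names only): 24823 probes matched by accession, 1191 by symbol and 472 by an older symbol, and 15919 kept the file's name. Probe positions are those of the files, on hg19. Which exon or untranslated region a probe lies in was not analysed here.

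Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes. The adjusted p-values given for genes come from this fit. Gene lists were tested with camera, two-sided, with a preset correlation of 0.01, adjusted over the lists with at least 5 tested members; 30 lists were written before the data were examined. A gene that was well above background on none of the 4 arrays of one group has only a bound there: the fold is then given as "at least", from the brighter group's mean against the higher, per array, of the dim signal and the lowest signal among probes well above background. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9.

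Genes named in the text follow a rule fixed before the data were examined: RFX6; the 10 largest rises and 10 largest falls at an adjusted p under 0.05 among genes with a symbol, non-overlapping groups and a measured level in both groups; up to 3 more each way with a bound in one group; up to 4 members of each list with the smallest adjusted p; and 20 beta cell and islet genes whatever their values, of which 2 are not reported here. The self-test used simulated data with 200 changed genes among 24427: the siRFX6 against siNT comparison recovered 41.8% of genes changed 1.5-fold, 64.2% at 2-fold and 93.9% at 4-fold, and it called 10 unchanged genes. The simulated noise was independent between genes and arrays, unlike noise that arrays or genes share, so these shares need not hold for the real data. The number of arrays limits the precision.

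Alternatives covered background correction, scaling, the filter on dim probes, the series table, array position, variance moderation, array weights, probe summaries, set tests and leaving out each array. After seeing the data, fits with the side of the slide (slide columns 1 and 2, or 3 and 4) as a block, fits within each side and row, and centring on probe GC content were added. Ranges of a gene's adjusted p over the alternatives leave out the series table as given and the fits within a side or row.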

Results

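The data are expression profiles of EndoC-βH2 cells after knockdown of RFX6, a winged-helix transcription factor of the islet lineage. Cells that received the RFX6 siRNA pool (siRFX6, 4 arrays) were compared with cells that received a non-targeting pool (siNT, 4 arrays), and the question was which transcripts differ when RFX6 is lowered. Between 67.1% and 78.4% of the spots on an array were well above background, and the groups had similar shares (72.1% ± 4.67 in siNT and 72.6% ± 3.73 in siRFX6, SD, n = 4). The study's own report dealt with calcium channels and insulin secretion, so lists on these subjects are not independent of it.

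RFX6 itself was lower on all 4 siRFX6 arrays. Its single probe, A_23_P327462, lies on chromosome 6 at 117253134 to 117253193 (hg19, plus strand). The level was 2.78 ± 0.05 in siNT and 1.49 ± 0.14 in siRFX6 (log2 relative to the array's 75th percentile, SD, n = 4). The log2 fold change of -1.29 (SE 0.081, limma adjusted p = 0.00109) leaves 40.9% of the control level (95% interval 35.9% to 46.6%). The exact two-sided permutation test of the level gave p = 0.0286, the smallest that 4 against 4 arrays allow. The log2 fold change was -1.38 within replicates 1 and 2 and -1.20 within replicates 3 and 4.

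**Figure D1:**
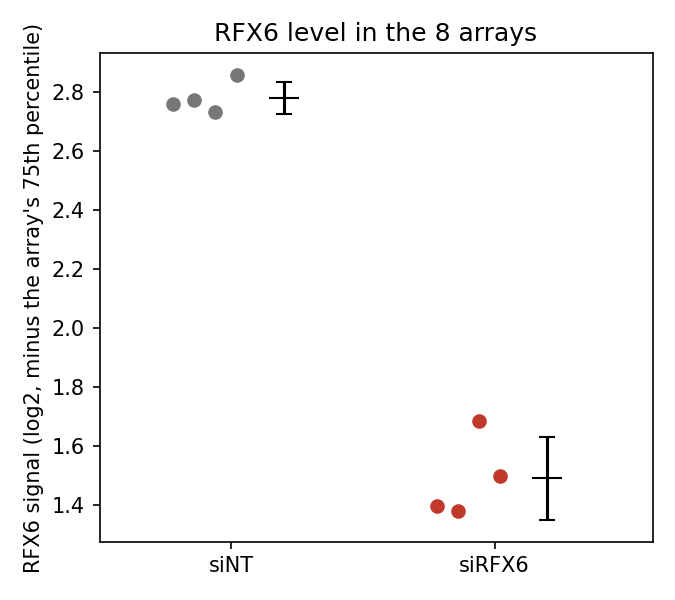
RFX6 signal on each array (log2, minus the array's 75th percentile) for siNT and siRFX6; points are arrays and bars are mean ± SD. The siRFX6 arrays held between 37.9% and 46.8% of the siNT mean.

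Across the transcriptome, 916 of 24427 genes differed at a limma adjusted p under 0.05. Of these, 623 were lower and 293 higher in siRFX6, and 489 changed by at least 1.5-fold (353 lower, 136 higher). The 2 groups did not overlap for any of the 916 genes, which selecting genes by this p-value itself favours, so it is no added evidence. They did not overlap for 11.7% of all tested genes, where chance gives 2.86%. The arrays of replicates 1 and 2, on one side of the slide, stood apart from those of replicates 3 and 4. With the side as a block 1900 genes passed (1252 lower); within replicates 1 and 2 no gene passed by limma (3346 at an unadjusted p under 0.05), and within replicates 3 and 4 107 did. All 107 had the same direction in replicates 1 and 2. The main count moved by over 1.5 times to 457 with median scaling, to 548 without the filter on dim probes, and when one array was left out: 574, 463 or 527 genes without siNT replicate 1, 3 or 4, and 508, 535 or 524 without siRFX6 replicate 2, 3 or 4.

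Among genes measured in both groups, the largest fall was that of RGS9, a regulator of G protein signalling, at a log2 fold change of -2.95 (SE 0.214, adjusted p = 0.00109). The matrix protein gene TNN (tenascin N), the peptide hormone gene CCK and the insulin-like growth factor binding protein gene IGFBP3 followed at -2.77, -2.74 and -2.67. FEV, a transcription factor of serotonergic neurons and endocrine precursors, was at -2.48. AIF1, RGS20, FHOD3, UBXN10 and FNDC11 completed the 10 largest falls, at log2 fold changes of -2.45 to -2.30. IGFBP3 was well above background on 1 and UBXN10 on 2 of 4 siRFX6 arrays, so their folds rest partly on signals near background. A dimmer AIF1 probe showed 0.19 with an adjusted p of 0.788. CYP4F3, LDLRAD1 and NNMT were not well above background on any siRFX6 array, and were at least 6.27-fold, 2.86-fold and 2.98-fold lower there (adjusted p = 0.0157, 0.00865 and 6.91e-05). When single arrays were left out, CCK no longer passed without siNT replicate 1, 3 or 4 or siRFX6 replicate 3 (adjusted p up to 0.0612), FNDC11 without any one siNT replicate or siRFX6 replicate 3 (up to 0.0757), and CYP4F3 without siNT replicate 1 or 3 (up to 0.0577).

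Among the 10 highest fitted rises, the phosphate transporter gene SLC17A1 was at a log2 fold change of 2.05 (SE 0.202, adjusted p = 0.00275). The sodium channel gene SCN7A rose by 2.01, AFF2 by 2.00, GADL1 by 1.87 and the potassium channel gene KCNJ8 by 1.83. PSTPIP1, NPAS3, MPPED1, DMBT1 and the amino acid transporter gene SLC3A1 rose by 1.74 to 1.55. Of 4 siNT arrays, SLC17A1 and GADL1 were well above background on 1, SCN7A on 2, and AFF2 and NPAS3 on 3, so the size and order of these rises rest partly on signals near background. DOK7 was not well above background on any siNT array and was at least 1.99-fold higher in siRFX6 (adjusted p = 0.0327). In the series table as given, AFF2, KCNJ8, PSTPIP1, MPPED1, DMBT1, SCN7A and SLC3A1 have the opposite sign, and each has a row there that holds another spot's values. AFF2 no longer passed without siNT replicate 1, 2 or 3 or siRFX6 replicate 3 or 4 (adjusted p up to 0.0806), DMBT1 without siRFX6 replicate 4 (0.0516), and DOK7 without siNT replicate 3 or 4 or siRFX6 replicate 2, 3 or 4 (up to 0.0973). The call of NPAS3 ended as a mean over its probes (adjusted p = 0.384, from 0.00265 over the alternatives).

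Among beta cell genes, the prohormone convertase gene PCSK1 was lower in siRFX6 at a log2 fold change of -0.72 (SE 0.090, adjusted p = 0.00593). The transcription factor gene PDX1 fell by 0.46 (SE 0.081, adjusted p = 0.0207). Over the alternatives the adjusted p of PDX1 lay between 0.0136 and 0.218, highest with median scaling. PDX1 no longer passed without any one siNT replicate or siRFX6 replicate 2 or 4 (adjusted p up to 0.0730). Insulin (INS) differed by -0.33 (SE 0.119, adjusted p = 0.253) and did not pass, nor did the sulphonylurea receptor gene ABCC8 at -0.57 (adjusted p = 0.0672) or the zinc transporter gene SLC30A8 at -0.46 (adjusted p = 0.362). NKX6-1, NKX2-2, MAFA, PAX6, NEUROD1, KCNJ11 and GIPR did not pass either, at log2 fold changes between -0.12 and 0.27, of which NKX2-2 was at 0.27 (adjusted p = 0.157) and NEUROD1 at 0.24 (adjusted p = 0.0662). For hormones of other islet cells, somatostatin (SST) was at -1.75 (SE 0.454, adjusted p = 0.0947) and glucagon (GCG) at 0.55 (adjusted p = 0.0855). With the side of the slide as a block, ABCC8, SLC30A8, NKX2-2, NEUROD1, SST and GCG passed (adjusted p = 0.00356, 0.00688, 0.0189, 0.0321, 0.00631 and 0.0164), and INS did not (adjusted p = 0.146). GLP1R was not well above background on any array and was not tested.

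**Figure D2:**
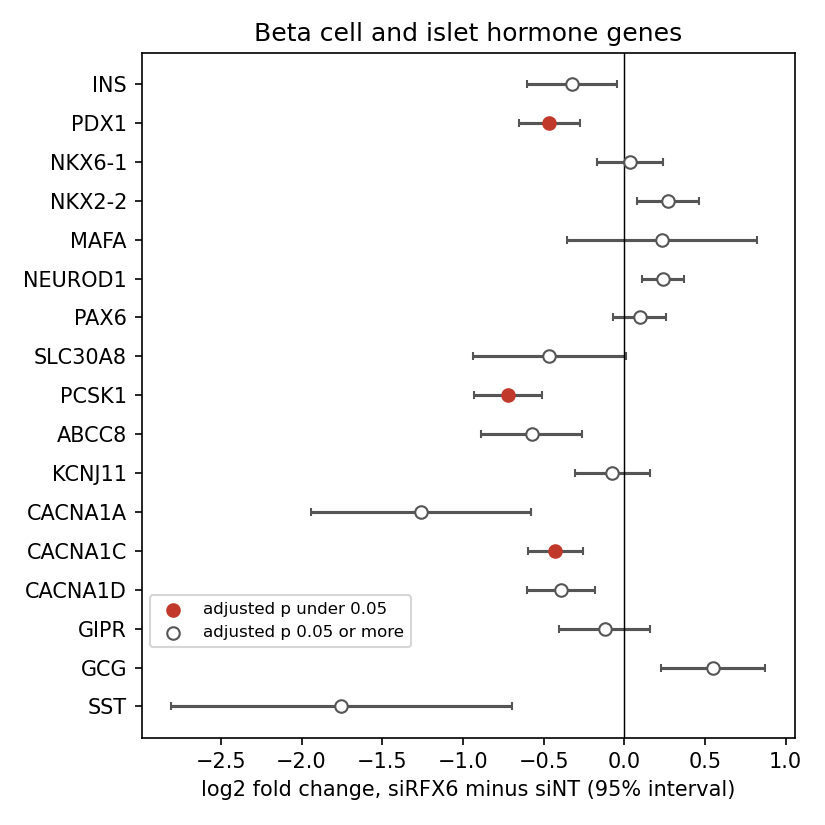
Log2 fold change (siRFX6 minus siNT, 4 arrays each) of beta cell and islet hormone genes, with 95% intervals; filled points have an adjusted p under 0.05. PCSK1, PDX1 and CACNA1C are filled and lie below 0, and INS lies at -0.33 with an open point.

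Of 17 tested voltage-gated calcium channel genes, 5 fell and none rose, and 15 had a log2 fold change below 0; adjusted over the list alone, 8 fell, a count that is not independent evidence because these channels were a focus of the study's own report. The pore subunit gene CACNA1C fell by 0.43 (SE 0.073, adjusted p = 0.0198), the beta subunit gene CACNB2 by 1.07 (SE 0.057, adjusted p = 0.00100), and CACNA2D1, CACNA2D2 and CACNA1B were at -0.58, -0.42 and -0.30; CACNA1B was named after its value was seen. CACNA1C no longer passed without siNT replicate 1, 3 or 4 or siRFX6 replicate 2 or 4 (adjusted p up to 0.0756), CACNA2D1 without siNT replicate 2, 3 or 4 or siRFX6 replicate 2, 3 or 4 (up to 0.0748), and CACNA2D2 without siNT replicate 3 or siRFX6 replicate 2 (up to 0.0516). Over the alternatives the adjusted p reached 0.0756 for CACNA1C, 0.0770 for CACNA2D1 with replicate as a block and 0.258 for CACNA2D2 with median scaling, from 0.00507, 0.00688 and 0.00332. CACNA1A was at -1.26 (adjusted p = 0.0663) and CACNA1D at -0.39 (adjusted p = 0.0610); CACNA1A has the opposite sign in the series table as given, where its row holds another spot's values. The list was lower by camera (adjusted p = 2.39e-05), with adjusted p = 0.0526 with an estimated correlation. Its median was -0.335 within replicates 1 and 2 and -0.18 within replicates 3 and 4, and its adjusted p was 9.3e-05 with the side of the slide as a block. With that block CACNA1A and CACNA1D passed as well (adjusted p = 0.00126 and 0.0497).

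Of 25 insulin granule genes, 4 fell and 1 rose (camera adjusted p = 9.32e-05, lower; adjusted p = 0.514 with an estimated correlation); adjusted over the list alone, 8 fell and 1 rose. SCGN, which encodes the calcium-binding protein secretagogin, fell by 0.97 (adjusted p = 0.00242), PCSK1 fell as above, and ERO1B, an oxidase of the endoplasmic reticulum, fell by 0.51 (adjusted p = 0.00837). PAM, an amidating enzyme named after its value was seen, was at -1.07. PCSK2, the other prohormone convertase gene, rose by 0.58 (adjusted p = 0.00904). With median scaling ERO1B and PCSK2 did not pass, at the highest adjusted p of their alternatives (0.00216 to 0.122 and 0.00241 to 0.0696). The list's median was -0.095 within replicates 1 and 2 and -0.231 within replicates 3 and 4.

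**Figure D3:**
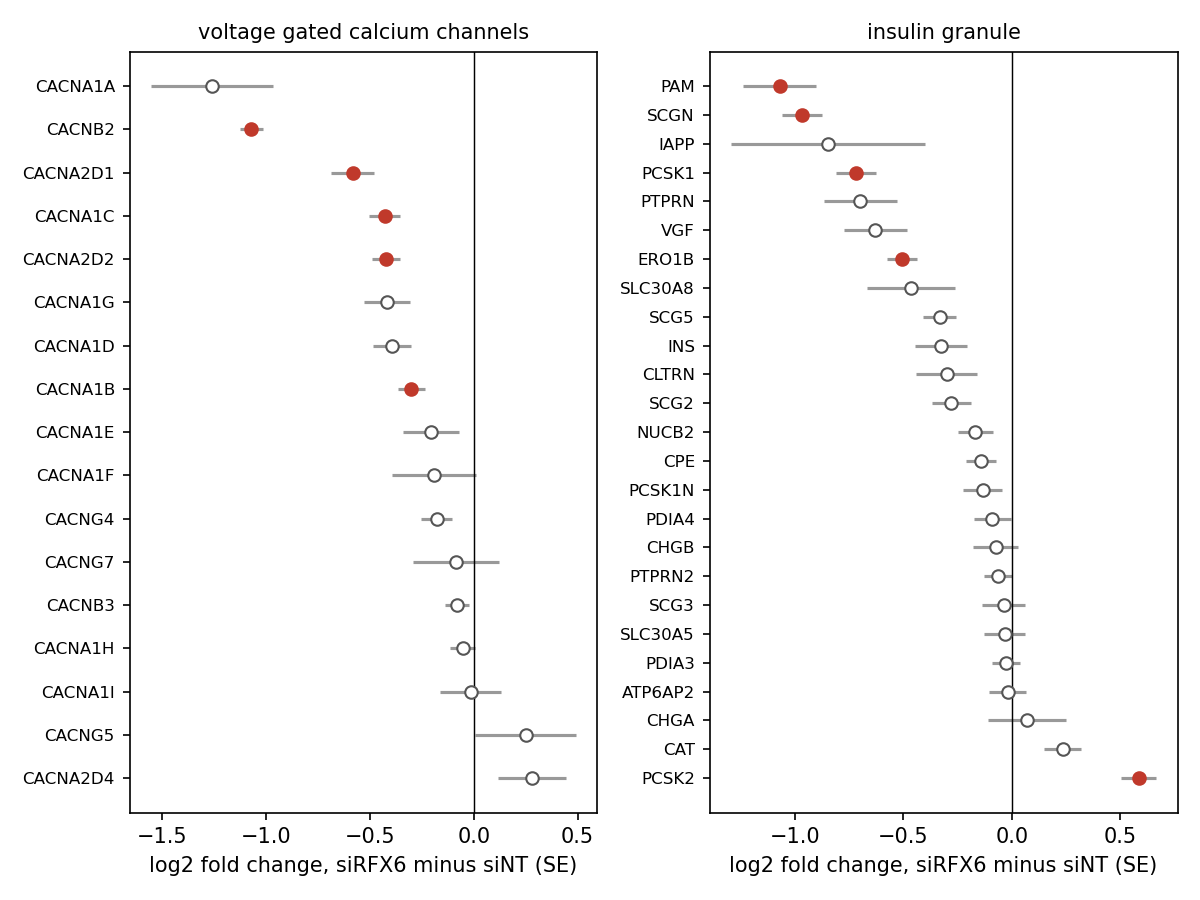
Log2 fold change (siRFX6 minus siNT, bars are SE, 4 arrays per group) of each tested gene of the calcium channel and insulin granule lists; filled points have an adjusted p under 0.05. In the first list 15 of 17 genes lie below 0, and in the second 22 of 25.

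A further 8 lists passed an adjusted p of 0.05. Incretin and other G protein-coupled receptor signalling was lower (7 of 35 genes fell, 2 rose, camera adjusted p = 0.0414; adjusted p = 0.374 with an estimated correlation), with RAPGEF4 at -0.69 and SSTR2 at -0.55, while the muscarinic receptor gene CHRM3 rose by 1.25 and RGS4 by 1.09. Potassium and sodium channels were lower (3 of 27 fell, 1 rose, camera adjusted p = 0.0359; adjusted p = 0.525 with an estimated correlation), with KCNC1 at -0.38, KCND1 at -0.39 and KCNN3 at -0.98, and KCNK17 at 0.57. Neuronal genes were lower (5 of 31 fell, 1 rose, camera adjusted p = 0.0459; adjusted p = 0.374 with an estimated correlation), among them NRXN2 at -0.66, NEFL at -0.48 and the vesicular monoamine transporter gene SLC18A2 at -1.73. The unfolded protein response list was lower (2 of 32 fell, camera adjusted p = 0.0359; adjusted p = 0.525 with an estimated correlation), with HSPA5 at -0.30 and XBP1 at -0.55. Immediate early genes were lower (2 of 21 fell, EGR4 at -1.90 and DUSP6 at -0.88, camera adjusted p = 0.0486; adjusted p = 0.525 with an estimated correlation). EGR4 also has the opposite sign in a displaced row of the series table. For cholesterol biosynthesis (25 genes, median -0.144, lower, adjusted p = 0.0334), cell cycle (41 genes, median 0.053, higher, adjusted p = 0.0334) and ribosomal proteins (44 genes, median 0.046, higher, adjusted p = 0.0359) no single gene passed; adjusted p = 0.689, 0.514 and 0.662 with an estimated correlation. With the side of the slide as a block, receptor signalling, potassium and sodium channels and the unfolded protein response (adjusted p = 0.0535 for each), neuronal genes (0.115) and immediate early genes (0.0822) no longer passed, while cholesterol biosynthesis, cell cycle and ribosomal proteins did (0.000213, 0.00748 and 0.0433). Single genes passed with that block too: FDPS, HMGCS1 and NSDHL of cholesterol biosynthesis and KIF23 of the cell cycle (limma adjusted p = 0.0279, 0.0345, 0.0439 and 0.0189). ACAT2, CCNA2, UBE2C, NUSAP1 and the ribosomal genes RPS3, RPS12, RPS23 and RPS19 did not. Of 19 planned settings outside the choice of set test, receptor signalling passed in 11, potassium and sodium channels in 9, neuronal genes in 10, the unfolded protein response in 13, immediate early genes in 3, cholesterol biosynthesis in 13, cell cycle in 14 and ribosomal proteins in 10, with adjusted p up to 0.162, 0.244, 0.162, 0.283, 0.457, 0.568, 0.186 and 0.735. With an estimated correlation none of the 29 tested lists passed. With fry, another planned set test, receptor signalling and neuronal genes passed (adjusted p = 0.000113 and 0.00288). Potassium and sodium channels, immediate early genes and the unfolded protein response did not (fry adjusted p = 0.0628, 0.0628 and 0.0782). Nor did cholesterol biosynthesis, cell cycle and ribosomal proteins (fry adjusted p = 0.374, 0.0734 and 0.303). Single genes depended on single arrays here too: KCND1, KCNK17, DUSP6 and XBP1 no longer passed without any one siNT replicate or siRFX6 replicate 2, 3 or 4 (adjusted p up to 0.0934, 0.0996, 0.0852 and 0.0914), HSPA5 without any one array (up to 0.113), and SLC18A2 without siNT replicate 3 or 4 (up to 0.0518). Over the alternatives the adjusted p reached 0.171 for KCND1, 0.108 for DUSP6, 0.211 for XBP1, 0.370 for HSPA5, 0.191 for KCNC1, 0.131 for NEFL and 0.109 for SSTR2, each with median scaling, and 0.0836 for SLC18A2 with replicate as a block. Adjusted over the list alone, 12 receptor signalling genes fell and 5 rose, 7 channel genes fell and 1 rose, 9 neuronal genes fell and 5 rose, 5 unfolded protein response genes fell and 2 immediate early genes fell.

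Among lists that did not pass by camera, islet transcription factors had 5 of 26 genes fall and none rise. These included PDX1, MLXIPL at -0.81, BACH2 at -1.03 and ISL1 at -0.43, the last named after its value was seen. RFX6 was kept out of this list and of the RFX family list. Exocytosis machinery had 5 of 37 genes fall, with RAB3B at -0.83, SYT4 at -0.60, SYT7 at -0.64 and RIMBP2, named after its value was seen, at -0.80, and SYT5 at least 1.93-fold lower (adjusted p = 0.00646); SYT7 no longer passed without siNT replicate 3 (adjusted p = 0.0538). Endocrine progenitor genes had 2 of 18 rise and 2 fall, with SOX4 at 0.66, DLL4 at 0.48, SOX11 at -0.59 and FEV as above. SOX4 no longer passed without siNT replicate 4 or siRFX6 replicate 2 or 4 (adjusted p up to 0.0576), nor did DLL4 without siNT replicate 3 or 4 or siRFX6 replicate 1, 2 or 4 (up to 0.0770). Over the alternatives the adjusted p reached 0.0818 for SYT4, 0.0736 for SOX4, 0.171 for DLL4 and 0.116 for MAF, each with median scaling, and 0.0692 for SYT7 with replicate as a block. Of 13 genes disallowed in mature beta cells, CXCL12 and CD44 were lower at -2.12 and -2.08 and MAF was higher at 0.35; of the 4 CXCL12 probes 3 were lower, and the dimmest was at 0.31 (adjusted p = 0.816). None of the 35 cilium assembly genes and none of 8 genes in the RFX family list passed in the main fit. With the side of the slide as a block, the cilium assembly genes IFT43 and IFT74 passed (adjusted p = 0.0412 and 0.0396), while CLUAP1 and SPAG6 did not (0.112 and 0.106). Among markers of other cell types, 1 of 12 haematopoietic genes fell (AIF1), 1 of 7 mesenchymal genes fell (COL5A1 at -0.42), acinar genes had 2 of 10 fall (PRSS2 at -1.30 and PRSS3 at -1.33) and 1 rise (SPINK1 at 0.40), and ductal genes had 1 of 16 fall (KRT19 at -0.68) and 2 rise (CLDN1 at 0.66 and SLC4A4 at 0.86). Over the alternatives the adjusted p reached 0.412 for COL5A1, 0.0562 for SPINK1 and 0.0699 for SLC4A4. Of 12 endothelial genes 4 were measured, too few to test as a list, and none of them passed. With fry, exocytosis machinery, islet transcription factors and mesenchymal genes passed as lists (adjusted p = 0.00117, 0.0278 and 0.0344). The median, mean and test differ in sign for other islet hormones, disallowed genes, acinar genes, p53 and apoptosis, interferon response, and hypoxia and glycolysis, of which none passed as a list. Of 26 interferon response genes, 2 fell (RSAD2 at -1.70 and ISG20 at -0.88) and 1 rose (OAS3 at 0.49). ISG20 no longer passed without any one siNT replicate or siRFX6 replicate 2, 3 or 4 (adjusted p up to 0.0975). OAS3 no longer passed without any one array (up to 0.122).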

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

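The test of spike-in probes, the tests of scaling and brightness behind the excess of falls, of the slide side behind the calcium channel list, and the count of splits for all changed genes were chosen after those results had been seen.

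Among 300 groups of 4 arrays (150 named genes in 2 treatments), 15 held an array far from the others, where chance gives about 5%. The gap to the nearest array as a share of the range was 0.902 for CACNA2D2 in siNT and 0.925 in siRFX6, 0.892 for COL5A1, 0.835 for COL6A1, 0.858 for ENO2, 0.922 for KCNJ11, 0.855 for KCNN3, 0.891 for OAS3, 0.928 for PAX6 and 0.842 for TNN in siRFX6, and 0.893 for EGR1, 0.907 for ENG, 0.852 for LOXL4, 0.88 for SCN7A and 0.9 for UBE2C in siNT.

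The arrays of replicates 1 and 2 stood apart from those of replicates 3 and 4, a split that cuts across the treatments. With quantile normalization 72.5% as many genes were called between the sides as the 4183 without it, and 62.8% of these 4183 were called in both, which argues against array brightness as the whole cause. Of the 4183, 71.2% were also called after centring on probe GC content, which argues against that content as the whole cause. The 10 spike-in probes differed by a median of 0.0793, which is 77.5% of the 0.102 of the 693 tested genes with as many as 10 spots; this leaves labelling or hybridisation open. A difference between culture or transfection rounds remains open and was not tested, since the labels name none.

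Of the 35 splits of the 8 arrays into 4 and 4, 2 gave as many changed genes as the real one (916), so chance is not excluded by this count. The other was the split by slide side, with 2783 genes, which points to a structure of the samples; the highest of the remaining splits gave 1. With a 1.5-fold minimum, 2 splits again reached the real 489, the highest other being 1502. With the side as a block, the real grouping called 1900 genes and the highest other of the 18 splits balanced over the sides called 0; 18 splits are too few for a share under 0.05. For gene lists, 4 of 35 splits gave as many as the real 10, the highest other being 10, so chance is not excluded for the number of lists.

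More genes fell than rose (68% of the calls). The lowest share over the planned scalings was 64.2%, which argues only against the choice among these scalings as the cause. They moved the median log2 fold change of all genes only between -0.0123 and 0.0189. Each aligns the arrays on their own signals, so a shift shared by most genes cannot be seen this way. In the brightest of 5 equal groups of genes the share of falls was 75%, which argues against signal near background. A biological effect of the knockdown and an effect of the siRNA pool on other transcripts stay open, and only 1 pool was used.

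For the calcium channel list, 0.02% of random lists matched on brightness and probe GC content had a mean as low, and the higher of the medians on the sides of the slide was -0.18. The share of random lists argues against member brightness and GC content. Each side holds 2 arrays of each group, so a difference between the sides cannot by itself lower the list. The medians show only that the list was lower on both sides. A fall of these channel genes after RFX6 knockdown stays a hypothesis, and off-target effects of the pool were not tested.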

How the results depend on the processing

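The block by side of the slide, the fits within each side and within each slide row, the series table without displaced rows and the centring on probe GC content were chosen after seeing the data.

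RFX6 was lower in every setting that gave a value, between -1.61 and -1.20. The -1.61 comes from the series table as given, where the RFX6 row holds another spot's values; without the genes of displaced rows that table gives none. Within 2 against 2 arrays, where fewer arrays are tested, it no longer passed: -1.38 in replicates 1 and 2, -1.20 in replicates 3 and 4, -1.28 in slide row 1 and -1.31 in slide row 2.

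The count of 916 genes became 457 with median scaling, 548 without the filter on dim probes, where more genes are tested, and 1900 with the slide side as a block. Leaving out 1 array gave 463 to 767. Within replicates 1 and 2, and within slide rows 1 and 2, limma called 0 genes (3346, 1211 and 2062 at an unadjusted p under 0.05), and 0 at 1.5-fold or more. Within replicates 3 and 4 it called 107, of which 107 changed at least 1.5-fold. The 489 genes changed at least 1.5-fold were 348 in the series table as given and 245 in it without displaced rows, which differ from the main setting in normalization too; the cause was not tested. With replicate as a block 744 genes passed, of which 563 were among the 916. Arrays of 1 number share a slide column, and their deviations from the group means correlated across genes by 0.27, 0.49, 0.32 and 0.033 for replicates 1 to 4; 3 of 8 arrays correlated best with the array of their own number. As 1 pair showed almost no correlation and the labels state no pairing, the arrays were not treated as pairs. Arrays of 1 number also lie on the same side of the slide, so these correlations cannot tell pairing from side. Whether the arrays were paired stays undecided.

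The 10 lists became 2 with median scaling, 4 with replicate as a block, 4 with array weights, 0 with an estimated correlation, 5 with the slide side as a block, 4 and 6 within replicates 1 and 2 and within replicates 3 and 4, 2 and 3 within slide rows 1 and 2, 3 with centring on GC content, and 3 to 10 when 1 array was left out. The calcium channel and insulin granule lists passed in 19 of 19 planned settings outside the choice of set test, with adjusted p up to 0.01 and 0.00873. The other 8 lists passed in 3 to 14 of them. With fry 7 lists passed: 6 of the 10 camera calls ended and 3 other lists gained one. The calcium channel and insulin granule lists passed with fry (adjusted p = 6.05e-05 and 0.0175). Except where the fit itself has fewer arrays or genes, the cause was not tested.

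Of the 84 genes that the naming rule picks and that passed, 41 also passed in every planned setting that tested them, and 84 kept their sign. Genes dim in 1 group, such as IGFBP3 and UBXN10, were not tested in the setting that required all 8 arrays above background. The series table as given was set aside for these counts. In that table signs reversed for AFF2 (-1.14), CACNA1A (1.23), DMBT1 (-1.79), EGR4 (1.26), KCNJ8 (-1.34), MPPED1 (-2.80), PSTPIP1 (-1.33), SCN7A (-0.38) and SLC3A1 (-2.06), each with a displaced row. IFT74 was at 0.0209 as a mean over probes, and NKX6-1 lay between -0.0154 and 0.0841 when 1 array was left out, with its sign changed in 1 of 8 cases; neither passed in the main setting.

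Lists that did not pass also changed direction, without passing; ranges over leaving out 1 array cover 8 cases, of which the number with a changed direction is given. These were p53 and apoptosis (adjusted p = 0.758 with median scaling, 0.879 as a mean over probes, 0.984 with fry, 0.769 with centring on GC content, and 0.497 to 0.990 leaving out 1 array, 3 changed), calcium stores (0.990 without the dim filter, 0.960 with replicate as a block, 0.833 with array weights, and 0.752 to 0.967 leaving out 1 array, 2 changed), endocrine progenitors (0.780 on probes above background on 8 arrays, 0.907 with array weights, and 0.756 to 0.902 leaving out 1 array, 3 changed), disallowed genes (0.899 without the dim filter, 0.849 with fry), acinar genes (0.780 on probes above background on 8 arrays), interferon response (0.909 on these probes, 0.634 with fry), hypoxia and glycolysis (0.252 to 0.998 leaving out 1 array, 2 changed) and other islet hormones (0.820 in the series table without displaced rows). The cause was not tested. Signals near background limit the genes called with 1 dim group.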

Other observations

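The test of motile cilium genes was set before its result was seen, on genes not noticed among the calls; the monoamine list was written after members had been seen among the calls, so no test of it is given.

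Several strongly lowered genes belong to the motile cilium, although none of the 35 cilium assembly genes fixed beforehand passed in the main fit. With the side of the slide as a block, the assembly genes IFT43 (-0.22) and IFT74 (-0.23) passed (limma adjusted p = 0.0412 and 0.0396). UBXN10 was at a log2 fold change of -2.35, and 13 such genes noticed among the calls had a median of -1.23. Among 57 further motile cilium genes 43 were below 0, 3 fell and none rose, with a median of -0.183. Camera put them lower at p = 2.99e-05 (p = 0.00672 with an estimated correlation), so a hypothesis is that motile cilium genes may fall together after RFX6 knockdown. Both p-values are unadjusted and come from the main fit only, so neither the side of the slide nor the scaling was varied. Camera with the preset correlation also passed up to 10 of the fixed lists in other splits of the arrays, which limits the first p-value. Other members of the RFX family regulate ciliary genes, and the RFX family genes measured here did not pass the test, which does not exclude a fall in them. Of the 8 tested, 5 were below 0 and 3 above. RFX2 was at -0.38 (SE 0.134, adjusted p = 0.230) and RFX3 at -0.17 (SE 0.250, adjusted p = 0.831). A dimmer RFX3 probe was at -0.49 (SE 0.183, limma adjusted p = 0.258 over all tested probes).

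Of 14 tested genes linked to monoamine synthesis, transport and breakdown, the transcription factor gene FEV included, 4 fell and 1 rose. The others did not pass. FEV, SLC18A2, PNMT and GCH1, which encodes the first enzyme of tetrahydrobiopterin synthesis, were at -2.48, -1.73, -1.20 and -1.34, and MAOB rose by 0.97. PNMT, GCH1, MAOB, TH and DDC were named after their values were seen. The tyrosine hydroxylase gene TH was at -0.26 (adjusted p = 0.404) and DDC at -0.03 (adjusted p = 0.865).

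The copy of the series table used here holds the values of another spot in 203 rows, that of RFX6 included. All 203 rows belong to spots with an absolute log2 difference of at least 0.98 between the treatments, and of 253 spots outside the controls with a difference of 1 or more, 199 were displaced. Whether this is so in the deposited record, or arose when the copy was prepared, is not known.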
